A study of Homo sapiens with 9 samples.

How the data were processed

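Gene expression of HL60 cells was measured on Illumina arrays from biotin-labelled total RNA extracted with a column kit, per the labels' protocols. The 9 libraries formed 9 groups of 1. The sort experiment held 4 of them (efflux-low, efflux-high, mock-sorted untreated and mock-sorted treated) and the bulk experiment held 5 (days 0, 1, 2, 7 and 17). Groups were taken from the sample titles. The dose of 10 nM and the 24 h exposure of the sort libraries came from the series title and design text.

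The deposited scanner table gives 1 intensity per gene and library on a linear scale, per the file headers without normalization, for 18401 genes. Background level and mean intensity differed between columns, which shows that the values were neither background-subtracted nor scaled. A detection p-value beside each deposited intensity gives the chance that the signal is background, per the file headers. For 79.0% of the rows these p-values were whole multiples of 1 in 309 within a tolerance of 0.01. A second deposited table of the authors' processed intensity values covered all but 7 of these genes. Within the 4 sort libraries and within the 5 bulk libraries the sorted values of its columns were the same, each column kept the rank order of its scanner column (rank correlation 1.0), and the gap to the mean of the sorted scanner values was at most 0.36%. The authors thus quantile normalized each set separately on the linear scale, with column medians of 68.98 to 68.99 for the sort set and 42.08 for the bulk set. No step of centring or log transformation was found in that table. The chip version, the scanner software and the way probes were summarized per gene are not given in the sources used here. No batch, slide or scan date was used. Every sample column was mapped by its name, and 0 further sample columns were left unused.

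Intensities were corrected for background by the normexp model, with the mean and spread of negative controls inferred in each library from the detection p-values of those rows whose p was a multiple of 1 in 309. An offset of 16 was added, and the 9 libraries were quantile normalized and log2 transformed with limma 3.58.1 in R 4.3.3. Where several rows shared an Entrez gene, the brightest represented it, leaving 18338 genes. Symbols are those of the array file, 18151 of 18401 rows matched a current gene of GRCh38.p14 through the Entrez number, and 14860 kept the same symbol. No genome build is named in the files, so cytobands are printed as the files give them and no coordinates are given. A gene entered a comparison if its detection p was below 0.01 in at least 1 of its libraries. Where a gene was not detected in a whole arm, its fold was given as a lower bound, from the mean of the bright arm against the higher of the dim gene's own value and the lowest detected value of that array, on the normalized log2 scale. No fold was given where this bound was below 1.

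The drug effect was fitted with limma (lmFit and eBayes with a trend, two-sided) on the mock-sorted pair and the day 0 and day 1 pair, with experiment as a fixed block. It had 4 libraries, 1 residual degree of freedom and 6.67 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over 8390 genes, and the same adjustment was made within each list. The 28 gene lists held 646 genes, of which 631 were on the array, and were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists. The other comparisons had 1 library per group and no test. They were described by the number of genes differing by 2-fold or more and by list medians, given as percentiles among 10000 random lists of the same size matched on mean expression in 20 bins, for lists with at least 5 detected members. The other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

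The scripts were tested on simulated data. For the drug fit on 8390 genes with 200 changed genes in each of 20 simulations, 79.1% of genes changed by 1 on the log2 scale were recovered, 99.7% of those changed by 2 and 100% of those changed by 3 or 4. Each simulated change was the same in both pairs, with independent normal noise, and 200 changed genes ease the adjusted threshold. Recovery in the measured data, where the 2 pairs differed in extent, can therefore be lower. False calls made up 11.2% of the calls at an adjusted p of 0.05, above the nominal share, and the limit at which this self-test stops was loosened after that share was seen. For random-list percentiles on 7458 genes of the day 2 comparison, 4 of 100 unshifted lists of 20 genes fell outside the central 95% of random lists, and 100 of 100 lists shifted by 0.5 lay above it.

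The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named ABCB1, then for the drug effect up to 10 genes per direction past an adjusted p of 0.05 with the same sign in both experiments, filled up from genes differing by 2-fold or more in both. For the efflux-high against efflux-low comparison and each bulk day it named the 10 highest and the 10 lowest differences, and in each list up to 4 members. Genes without a symbol and identifiers starting with LOC or HS. were left out of the names. The rule was also applied to the mock-sorted pair and to the efflux-high against mock-sorted treated comparison after their values were seen. Persistence and correlation across genes were computed only between differences that share no library. Alternatives were no background correction, an offset of 50, centring each array on its median, the authors' processed table, stricter and absent detection filters, every row counted, other forms of the drug fit, an estimated correlation and a threshold of 1.5-fold. Chosen after the data were seen were normalization without the efflux-low library and centring on the 5249 genes detected in the other 8 libraries. The number of arrays, 1 per group, limits the precision of every value.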

Results

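Total RNA from HL60 cells, a human promyelocytic leukaemia line, was measured on Illumina expression arrays in 9 libraries, 1 per group. Vincristine, a vinca alkaloid that binds tubulin and blocks microtubule assembly, was given at 10 nM for 24 h. In the sort experiment, treated cells were separated by their export of calcein AM, a dye ester pumped out by ABC transporters, into an efflux-low and an efflux-high fraction, and a treated and an untreated culture were mock sorted. In the bulk experiment, cells were sampled untreated at day 0, at the end of the drug exposure at day 1, and at days 2, 7 and 17 after the drug had been washed out at day 1. Of 18401 genes, between 5673 and 7764 had a detection p below 0.01 in 8 libraries. Mean raw intensity lay between 248.9 and 303.7 in 6 of these 8 libraries and was 137.1 at day 1 and 112.4 at day 7.

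The efflux-low library stood apart from the other 8. It had 1135 detected genes (6.2%). Its mean background was 141.6 intensity units against 28.6 to 40.9 in the others. ACTB, which encodes cytoplasmic beta-actin, read 244 units against 4380 to 12695, and GAPDH, a glycolytic enzyme, read 274 against 1600 to 7828. MPO, the myeloperoxidase of promyelocyte granules, read 228 against 7256 to 22099. The median ribosomal protein gene lay 3.07 times above background, against 95.9 to 284 times in the other libraries. The rank correlation of this library with any other was at most 0.39 across genes, and the other 8 correlated with each other at 0.88 or more.

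**Figure D1:**
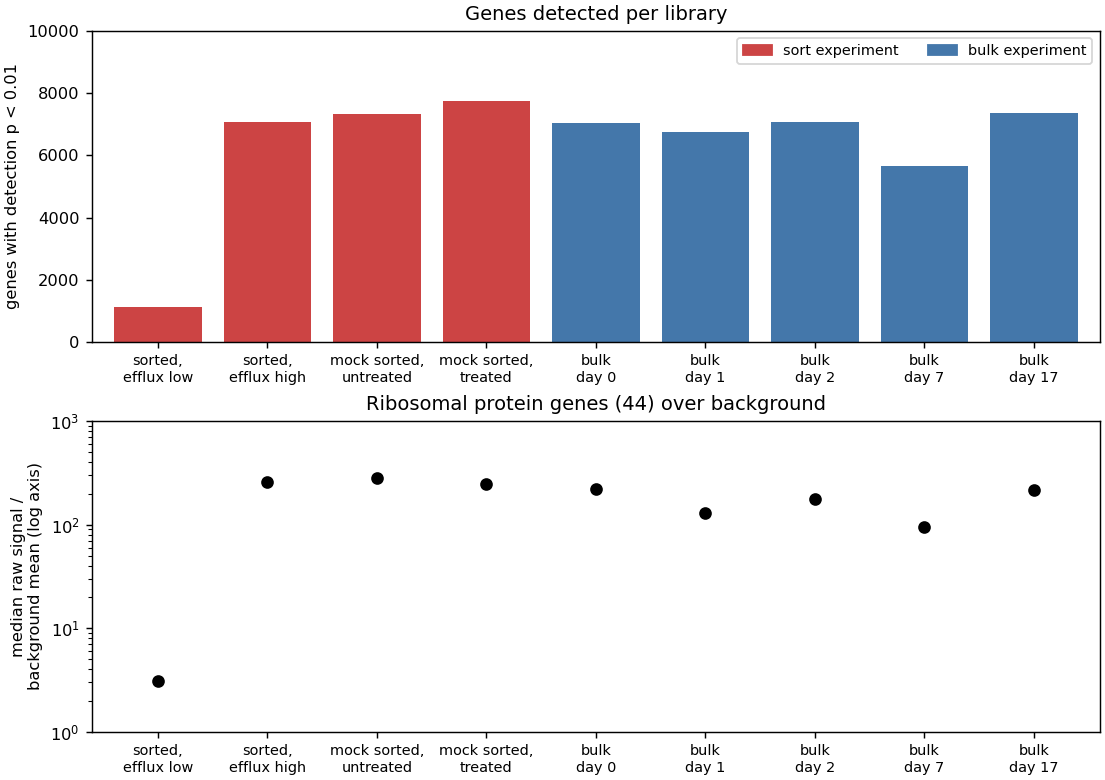
Number of genes with a detection p below 0.01 (upper panel, bars) and median raw signal of 44 ribosomal protein genes over mean background on a log axis (lower panel, points), for each of the 9 libraries. The efflux-low library had 1135 detected genes and a ratio of 3.07, below all others.

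ABCB1 (7q21.12a-q21.12b), the pump that exports both vincristine and calcein AM, was not detected in any of the 9 libraries. Its detection p ranged from 0.469 to 0.958. Its raw intensity was between 25.9 and 35.6 in 8 libraries and 135.3 in the efflux-low library, below mean background in each. No fold was computed for it. Of the 16 ABC transporter genes in the list fixed for this family, 8 were detected in the sort pair, and 0 of these differed by 2-fold or more. In the efflux-high against the mock-sorted treated library, the list median relative to all genes was -0.21, and -0.26 when arrays were centred on a median. With undetected genes held at the detection limit, the median was -0.02, with 0 of 8 members 2-fold or more higher and 1 lower. ABCC4, which encodes a pump of cyclic nucleotides and drugs, differed by -0.08 in the sort pair and -0.88 at day 1.

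The contrast between treated and untreated cells addressed which transcripts differed after 24 h in the drug. Of single genes, 3 chemokine genes, CD14 and LGALS1 rose. CCL2 (17q12a), a monocyte-attracting chemokine, rose by 3.95 on the log2 scale (SE 0.26, n = 2 libraries per arm, limma adjusted p = 0.00412), with 4.42 in the mock-sorted pair and at least 9.8-fold in the bulk pair, where it was not detected at day 0. CD14 (5q31.3b), the lipopolysaccharide co-receptor of monocytes, rose by 2.73 (SE 0.26, limma adjusted p = 0.0242). CXCL8 (4q13.3d, listed as IL8), the neutrophil-attracting chemokine interleukin-8, rose by 2.57 (SE 0.27), and CCL3L3 (17q12b), a chemokine gene with near-identical copies that one probe may not separate, rose by 2.43 (SE 0.26), both with a limma adjusted p of 0.0313. LGALS1 (22q13.1a), the gene of galectin-1, rose by 1.80 (SE 0.16, limma adjusted p = 0.0221), with 1.84 and 1.77 in the 2 experiments.

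Those 5 genes passed and 0 genes fell among 8390 tested by limma. At an unadjusted p below 0.05, 364 genes were higher and 264 lower. CCL2 and CCL3L3 were detected in 1 of the 2 untreated libraries, so their fitted differences and standard errors rest in part on a day 0 value not above background. By size alone, 21 genes were 2-fold or more higher in both experiments, 1 was lower in both and 0 moved in opposite directions, where independent lists would share 0.44 and 0.09 genes. Of the 21, the largest that did not pass were FOSB, an AP-1 transcription factor subunit (2.35, limma adjusted p = 0.207), HP, which encodes haptoglobin (2.07, limma adjusted p = 0.141, detected in 1 of the 2 untreated libraries), and RGS2, a regulator of G protein signalling (2.03, limma adjusted p = 0.209). NCF1, a subunit of the phagocyte NADPH oxidase, was at least 3.96-fold higher (limma adjusted p = 0.184) and the chemokine CCL3 at least 3.56-fold higher (limma adjusted p = 0.0669), since neither was detected in untreated cells. The gene lower in both was ASS1, argininosuccinate synthase (-1.44, SE 0.20, limma adjusted p = 0.0729). The fit had 1 residual degree of freedom, and normalizing without the efflux-low library, a choice made after the data were seen, left 2 of the 5 calls, CCL2 and LGALS1, while centring on the median of all genes gave 75 calls (68 higher), centring on detected genes 125 (83 higher) and a fit without the experiment block 0. Nothing in the labels says that the 2 experiments came from separate cultures, so these p-values measure only the spread between these libraries, which may be technical.

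**Figure D2:**
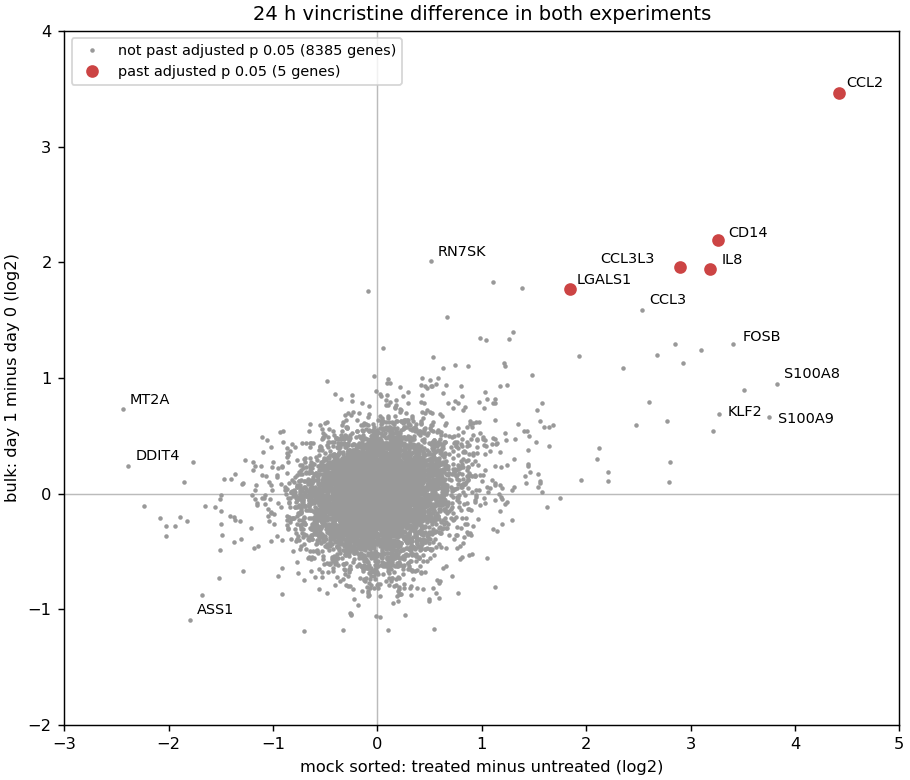
Log2 difference of each of 8390 genes between treated and untreated cells in the mock-sorted pair (x axis) and between day 1 and day 0 in the bulk pair (y axis), with 5 genes past a limma adjusted p of 0.05 in red. CCL2 lies at 4.42 and 3.47, the second measured against an undetected day 0 value, while S100A8 and S100A9 lie at 3.83 and 3.75 on the x axis and at 0.95 and 0.66 on the y axis.

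Of 28 gene lists fixed before the data were examined, 12 differed from the other genes in the limma camera test. At the preset correlation of 0.01 this test treats genes as nearly independent, although only 4 libraries entered. Its p-values, however small, therefore do not measure the spread between cultures. With an estimated correlation this test has only the 1 residual degree of freedom, so a list could hardly pass whatever its correlation. Apoptosis genes, at an estimated correlation of 0.011 near the preset 0.01, went from an unadjusted camera p of 0.00632 to 0.225. Other called lists had estimates from -0.046 (cholesterol synthesis) to 1 (heat shock and NRF2 targets), with 0.275 for inflammatory and 0.463 for AP-1 genes. These estimates rest on the same 1 degree of freedom, and the preset may be too low for some lists. The losses given below thus do not tell whether correlation between genes accounts for the calls. The list of NF-kB and inflammatory genes rose (median 1.02, with 1.07 in the sort and 0.73 in the bulk pair, 14 genes tested, adjusted p = 8.18e-18), with 3 members past the test over all genes and 9 up when adjusted over the list alone, and was lost at adjusted p = 0.738 with an estimated correlation. The mature myeloid list rose (median 0.75, with 0.98 and 0.20 in the 2 pairs, 21 genes, adjusted p = 5.34e-15), with 1 member past over all genes and 13 up when adjusted over the list alone, and was lost at adjusted p = 0.738 with an estimated correlation. In the sort pair, S100A8 and S100A9, the subunits of calprotectin, were higher by 3.83 and 3.75, and at day 1 by 0.95 and 0.66. CD86, a costimulatory receptor, was higher by 0.98 and 1.35, and CSF1R, the receptor for macrophage colony-stimulating factor, by 1.02 and 0.74.

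The AP-1 and immediate-early list rose (median 0.54, with 0.62 and 0.10 in the 2 pairs, 20 genes, adjusted p = 2.18e-07), with 0 members past over all genes and 7 up when adjusted over the list alone, and was lost at adjusted p = 0.738 with an estimated correlation. The lysosome and autophagy list rose (median 0.31, 23 genes, adjusted p = 5.35e-08), with 0 and 1, led by the cathepsins CTSD (1.31 in the sort pair, 0.30 at day 1) and CTSZ (1.11 and 0.48), and was lost at adjusted p = 0.738 with an estimated correlation. FOSB was higher by 3.41 in the sort pair and 1.29 at day 1. KLF2, a Krueppel-like factor, and EGR1, an immediate-early zinc finger factor, were at least 9.37-fold and at least 9.10-fold higher in the sort pair, where neither was detected in untreated cells.

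Cholesterol synthesis genes fell as a list (median -0.39, 18 genes, adjusted p = 2.47e-05), with 0 members past over all genes and 1 down when adjusted over the list alone, and were lost at adjusted p = 0.738 with an estimated correlation. HMGCS1, which makes hydroxymethylglutaryl-CoA, differed by -0.76 in the sort pair and -0.69 at day 1. Ribosomal protein genes fell slightly (median -0.13, 43 genes, adjusted p = 0.00205), as did G1/S and replication genes (median -0.13, 24 genes, adjusted p = 0.0446), the first with -0.19 in the sort and -0.02 in the bulk pair and the second with -0.04 and -0.19. Both had 0 members past over all genes and 0 when adjusted over the list alone, and were lost at adjusted p = 0.738 with an estimated correlation.

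With an estimated correlation the 5 remaining lists that rose were lost too, NRF2 targets at adjusted p = 0.829 and the other 4 at adjusted p = 0.738 with an estimated correlation. They were cytoskeleton and adhesion (median 0.15, adjusted p = 8.75e-05, 1 member past over all genes and 2 up when adjusted over the list alone), heat shock (0.30, 0.0015, 0 and 3), myeloid transcription factors (0.14, 0.0123, 0 and 0), apoptosis (0.18, 0.0177, 0 and 0) and NRF2 targets (0.17, 0.038, 0 and 0). In the sort and bulk pairs the medians were 0.34 and 0.01 for cytoskeleton, 0.51 and 0.07 for heat shock and 0.40 and -0.09 for NRF2 targets. When arrays were centred on the median of all genes, the calls of heat shock (0.09 relative to all genes, adjusted p = 0.197), NRF2 targets (0.03, 0.692), apoptosis (0.25, 0.152) and G1/S genes (-0.26, 0.119) were lost.

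The other 16 lists did not pass, although centring on the median of all genes called 4 of them (tubulins at adjusted p = 0.0262, p53 targets at 0.0229, endoplasmic reticulum and ATF4 stress at 0.0229 and stem genes at 0.0262), and centring on detected genes called the stress list (5.88e-06) and ribosome biogenesis (0.00104). Stress-response genes of the endoplasmic reticulum and the ATF4 pathway had a median of -0.20 (camera adjusted p = 0.0648), ribosome biogenesis -0.08 (0.0992), replicative histones 0.13 (0.148) and interferon response 0.15 (0.161). Stem and progenitor genes had a median of 0.10 (0.162), p53 targets 0.02 (0.338), tubulins -0.13 (0.516) and mitosis genes -0.01 (0.688). The Wnt list, which holds targets and pathway components such as FZD7 and GSK3B, had a median of -0.11 (0.526). ABC transporters had a median of -0.02 (0.783), which turned to 0.06 relative to all genes when arrays were centred on a median. Oxidative phosphorylation had a median of 0.11 (0.162), which turned to -0.11 relative to all genes when arrays were centred on a median instead of quantile normalized. Promyelocyte granule genes (0.3, turning from 0.01 to -0.13 relative to all genes when centred), drug metabolism (0.683), glycolysis and hypoxia (0.876) and lymphoid markers (0.974) had a median that differed in sign from the mean or from the test. Erythroid and megakaryocyte markers (0.808), another lineage, had 2 detected members, whose median of -0.05 turned to 0.14 relative to all genes when centred.

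The sort and bulk pairs differed in extent. In the sort pair 118 genes were 2-fold or more higher and 69 lower, and at day 1 of the bulk experiment 31 were higher and 11 lower. Relative to the median of all genes, the sort pair had 118 higher and 68 lower. These became 73 and 40 without background correction, 60 and 37 with an offset of 50, and 65 and 38 in the authors' table. Centring on a median gave 154 and 71. Mitosis genes had a median of -0.19 in the sort pair (percentile 0.9 of random lists) and 0.10 at day 1 (percentile 96.1), the latter turning to -0.01 relative to all genes when arrays were centred on a median. Heat shock genes had a median of 0.51 in the sort pair (percentile 100), led by HSPA1B (1.45), and 0.00 at day 1 (percentile 49.8). Tubulin genes had a median of -0.23 at day 1 (percentile 0.9) and 0.01 in the sort pair (percentile 54.8), the latter turning to -0.23 relative to all genes when centred. Libraries of 1 condition differed more between the experiments, with 285 genes 2-fold higher and 210 lower in the mock-sorted untreated library than at day 0, and 391 and 363 between the treated libraries.

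The bulk time course followed the cells through the pulse and 16 days after it, and no test was run because each day had 1 library. At days 1 and 2 the highest differences included those of CCL2, CD14, CXCL8 and the non-coding RNA gene RN7SK. CCL2 was at least 9.8-fold higher than at day 0 at day 1, at least 8.63-fold at day 2, at least 3.0-fold at day 7 and at least 2.63-fold at day 17. CD14 was higher by 2.19, 2.65, 2.07 and 1.01 on the log2 scale, and CXCL8 by 1.94, 2.29, 2.13 and 1.21. GBP2, an interferon-inducible GTPase, was higher by 1.78 and the exonuclease gene ISG20 by 1.75 at day 1. S100A8 was higher by 2.01, S100A9 by 1.92, PADI4, a histone-citrullinating enzyme of granulocytes, by 2.21 and TNF by 1.68 at day 2, and OLR1, a scavenger receptor, was at least 3.5-fold higher.

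Single genes of metabolism at days 1 and 2, and single ribosomal protein genes at day 2, were among the lowest. ASS1 differed by -1.09, the sorbitol dehydrogenase gene SORD by -1.18 and FAHD2A by -1.19 at day 1. At day 2, CYP51A1, the sterol demethylase, differed by -1.84, HMGCS1 by -1.56, the cholesterol exporter gene ABCA1 by -1.75, the signalling adaptor gene PIK3AP1 by -1.59, and the ribosomal protein genes RPL14 and RPL23 by -1.69 and -1.57. The cholesterol synthesis list had a median of -0.48 at day 2, with 0 of 18 members higher and 3 lower by 2-fold or more (percentile 0.0 of random lists). The median was -0.28 at day 1 (0.0), 0.05 at day 7 (75.4) and -0.19 at day 17 (1.5), and the day 7 value turned to -0.11 relative to all genes when arrays were centred on a median. The non-coding 7SK RNA, RN7SK, was higher by 2.01 at day 1 and 3.32 at day 2.

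At day 7 chemokine genes and several ATF4 pathway genes were higher. CCL3L3 was at least 5.71-fold and CCL3 at least 4.49-fold higher than at day 0, with the same caution on near-identical copies. DDIT4, an inhibitor of mTORC1 signalling, was higher by 1.88, the metallothionein gene MT2A by 1.85 and the glycolytic aldolase gene ALDOC by 1.71, and SESN2, a stress-induced sestrin, was at least 2.1-fold higher. Of the 17 detected members of the endoplasmic reticulum and ATF4 list, 5 were 2-fold or more higher and 0 lower (median 0.60, percentile 100), among them DDIT3 (1.20) and ASNS (1.04), which encodes asparagine synthetase, while the chaperone genes HSPA5 (-0.35) and CALR (-0.30) of the endoplasmic reticulum were lower. Heat shock genes had a median of -0.54 (percentile 0.0), with HSPE1 at -1.01 and HSPA8 at -0.97. PTMA, the prothymosin alpha gene, was the lowest at -1.54. The day 7 array was the dimmest of the bulk set, and of 60 genes 2-fold or more lower, 10 remained when genes undetected at day 7 were held at the detection limit.

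At day 17 metallothionein genes, whose products bind zinc and copper, had the highest differences. MT1H was higher by 2.66, MT1G by 2.65, MT2A by 2.34, MT1A by 1.89 and MT1X by 1.71, and these closely related genes can share probe signal. TNF was higher by 1.59. LYZ, which encodes lysozyme, differed by -1.94, ABCA1 by -1.83, the linker histone gene HIST1H1C by -1.60, RPL14 by -1.44 and B2M, the light chain of class I molecules, by -1.37. Mitosis genes had a median of -0.31 (28 genes, percentile 0.0 of random lists), with NEK2, a centrosomal kinase, at -1.05. Over the time course, 31, 53, 43 and 23 genes were 2-fold or more higher and 11, 54, 60 and 43 lower at days 1, 2, 7 and 17. Centring arrays on a median shifted the median of all genes by -0.56, -0.95 and 0.33 at days 1, 7 and 17, and with this shift gave 567, 3244 and 226 genes, of which 1.8, 0.1 and 94.2% were higher. All 4 differences share the day 0 library, so chance values of that library enter each of them.

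**Figure D3:**
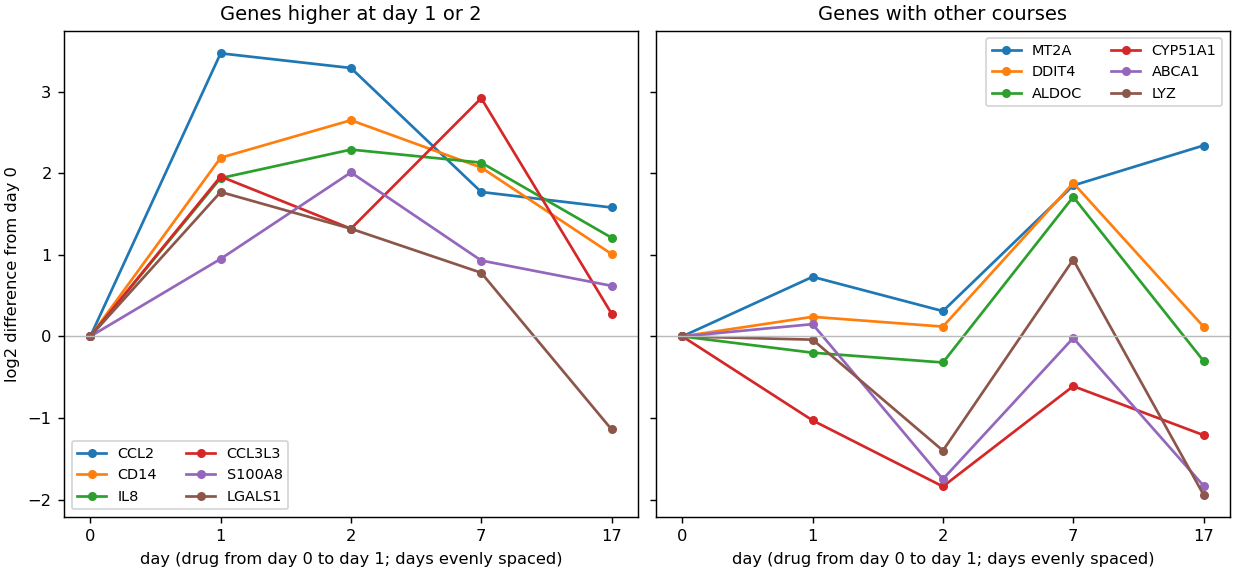
Log2 difference from day 0 (y axis) of 12 genes at days 0, 1, 2, 7 and 17 of the bulk experiment (x axis, evenly spaced), with 1 library per point. CD14 stood at 2.19, 2.65, 2.07 and 1.01, and MT2A reached 2.34 at day 17; CCL2 and CCL3L3 were not detected at day 0, so their points are measured differences and not bounds.

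The inflammatory list stayed above random lists at every later time, over its members detected in each comparison. Its median was 0.88 at day 1, 0.77 at day 2, 1.42 at day 7 and 0.51 at day 17 (percentile 100 at each), or 0.58, 0.66, 1.05 and 0.23 with undetected genes held at the detection limit. Mature myeloid genes had medians of 0.66, 0.61, 0.50 and 0.01, or 0.46, 0.33, 0.50 and 0.01 held in the same way, the last at percentile 48.8 and with a sign that depended on the scaling. AP-1 genes had medians of 0.28, 0.36, 0.22 and 0.05, and lysosome genes of 0.26, 0.31, 0.12 and 0.07. Relative to all genes, AP-1 medians of 0.29, 0.35, 0.23 and 0.04 became 0.56, 0.38, 0.69 and 0.03 when arrays were centred on a median. Interferon response genes had medians of 0.37, 0.33, 0.24 and -0.16, the first at percentile 100 and the last at 13.5, and -0.04 in the sort pair, which turned to 0.01 relative to all genes when arrays were centred on a median. The members changed between days, with 13, 12, 11 and 9 inflammatory and 16, 20, 14 and 16 mature myeloid genes. Members undetected at day 0 entered only where the later library detected them, and random lists were drawn under the same filter. At day 1 the AP-1 median covered 12 genes. Over all 21 mature myeloid and 20 AP-1 genes of the drug test, the day 1 medians were 0.20 and 0.10.

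**Figure D4:**
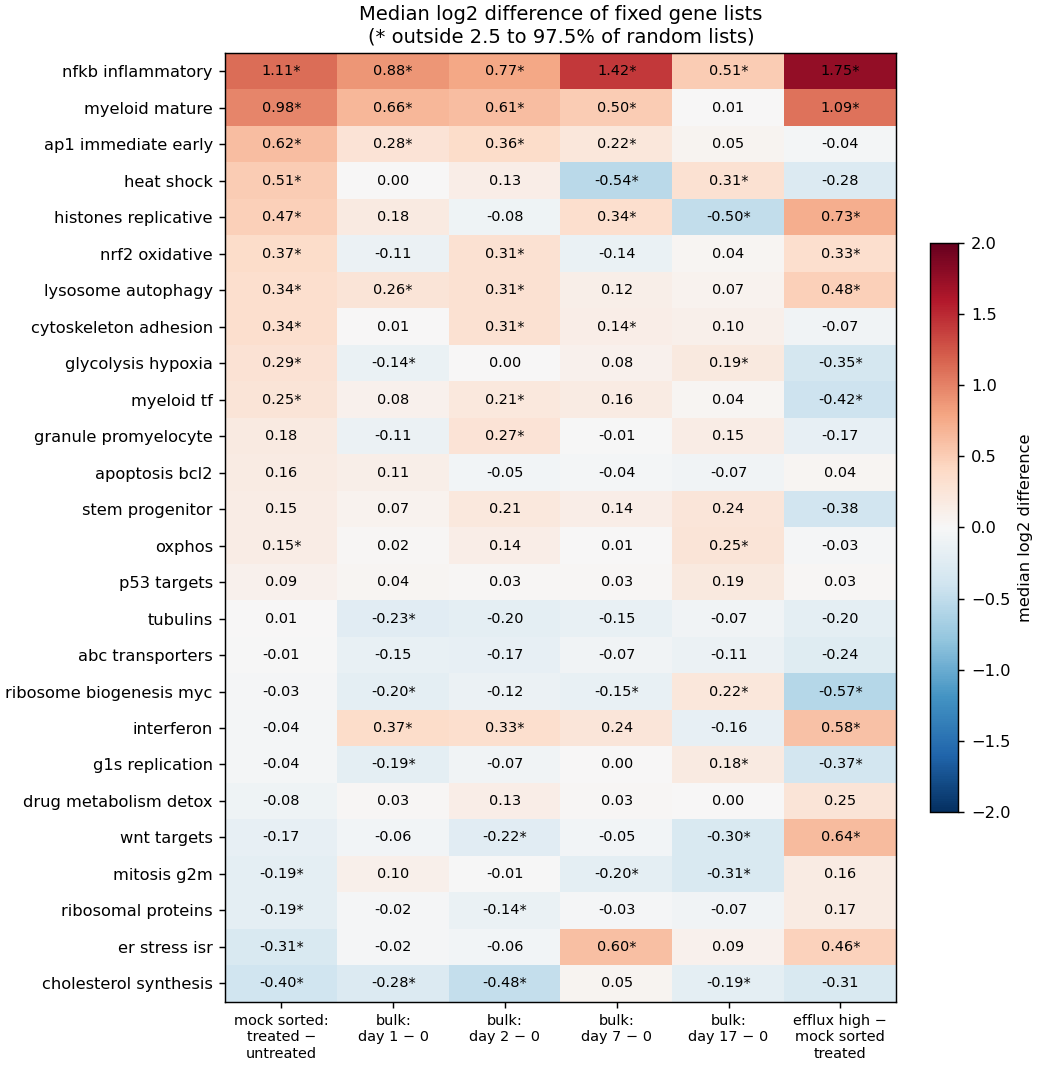
Median log2 difference of 26 fixed gene lists (rows) in 6 comparisons (columns), with colour from -2 to 2 and an asterisk where the median lay outside the central 95% of 10000 random lists of matched expression. The inflammatory list ranged from 0.51 at day 17 to 1.75 in the efflux-high fraction.

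The 118 genes higher in the mock-sorted pair were then followed in the bulk libraries, which share no library with that pair. Their median difference from day 0 was 0.43 at day 1, 0.61 at day 2, 0.08 at day 7 and 0.09 at day 17, and 85.6, 89.0, 63.6 and 66.9% of them were higher at those days. The later medians depended on the scaling, since relative to all genes they were 0.65, 0.65, 0.57 and -0.05 when arrays were centred on a median, against 0.44, 0.61, 0.09 and 0.07. The 69 genes lower in the sort pair, led by MT2A (-2.44), DDIT4 (-2.39), PCK2 (-2.24), PHGDH (-2.08), ATF5 (-2.03) and ASNS (-1.94), had medians of -0.08, -0.10, 0.42 and -0.04, and relative to all genes the same 69 genes kept these signs under centring (-0.06, -0.14, 0.51 and -0.08), while genes chosen anew after centring had 0.06 at day 1. At day 7, 14.5% of these 69 were lower and 12 were 2-fold or more higher. PCK2, PHGDH and ASNS encode enzymes of gluconeogenesis, serine synthesis and asparagine synthesis. The naming rule was applied to this pair after its values had been seen. Across genes, which are not independent replicates, the sort difference had a Pearson correlation of 0.24 with day 1 (Spearman 0.14), 0.32 with day 2 (0.24), -0.14 with day 7 (-0.23), which became 0.00 when arrays were centred on a median, and 0.14 with day 17 (0.15).

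The sorted fractions addressed how treated cells with high and low dye efflux differed. In the efflux-high library, inflammatory genes were higher than in the mock-sorted treated library. SPP1, which encodes osteopontin, was higher by 4.47, MMP9, a matrix gelatinase, by 3.78, IL1B by 3.30 and TMEM158 by 3.12. CXCL5, a neutrophil-attracting chemokine, was at least 7.91-fold higher and HMOX1, the haem-degrading oxygenase, at least 11-fold higher, neither being detected in the mock-sorted library. Probes for ferritin heavy chain pseudogenes (FTHL7 3.48, FTHL3P 3.40, FTHL12 3.17) may read transcripts of the parent gene and are uncertain.

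Of the 15 detected inflammatory genes, 10 were 2-fold or more higher and 0 lower (median 1.75, percentile 100), among them CCL2 (2.43), PTGS2 (2.17), CCL5 (2.08) and PLAUR (1.75). Mature myeloid genes had 11 of 21 higher and 0 lower (median 1.09, percentile 100), such as FPR1 (2.68), CD14 (2.43) and LYZ (1.91). Lysosome genes had 9 of 25 higher (median 0.48, percentile 100), such as CTSH (1.98), CTSB (1.78) and SQSTM1 (1.59). NRF2 targets had 3 of 14 higher (median 0.33, percentile 99.5), including NQO1 at least 6.76-fold. Interferon genes had a median of 0.58 (percentile 99.8), with IFI6 at 1.72. The Wnt list, which holds targets and pathway components, had 2 of 10 higher (median 0.64, percentile 100), namely JUN (1.89) and CD44 (1.75). JUN is also in the AP-1 list and CD44 in the cytoskeleton and adhesion list.

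Ribosome biogenesis and myeloid transcription factor genes were lower as lists in the efflux-high library, as were single granule genes. PRTN3 and MPO, which encode the granule proteins proteinase 3 and myeloperoxidase, differed by -2.70 and -2.02 from the mock-sorted treated library, and AZU1 by -1.70, while the granule list as a whole had a median of -0.17 (percentile 13.6) that turned to 0.08 relative to all genes when arrays were centred on a median. Ribosome biogenesis genes had 7 of 26 lower and 0 higher (median -0.57, percentile 0.0), such as RRP1B (-1.57), SRM (-1.44) and PA2G4 (-1.36). Myeloid transcription factors had 4 of 16 lower and 2 higher (median -0.42, percentile 0.7), with IRF8 at -1.73, SPI1 at -1.34 and CEBPA at -1.27. The AP-1 list as a whole had 2 of 20 higher and 2 lower by 2-fold or more (median -0.04), with undetected genes held at the detection limit. Of its members, KLF4 (-1.53), also in the myeloid transcription factor list, and FOS (-1.14) were lower, while JUN, given above, was higher. CITED4 differed by -2.06 and MYST3, a histone acetyltransferase gene, by -1.95. In all, 356 genes were higher and 305 lower by 2-fold or more against mock-sorted treated cells, and 451 and 351 against mock-sorted untreated cells. By comparison, 391 genes were higher and 363 lower in the mock-sorted treated library than at day 1, which are treated libraries of different experiments. Mock-sorted cells were not split by efflux, so these counts are not a contrast of high with low efflux. Genes were named for this comparison by the rule after its values were seen. No test was possible with 1 library per group.

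The direct comparison of the fractions rested on the near-background efflux-low library. Among the highest genes in the efflux-high library were TYROBP, a signalling adaptor of myeloid receptors (at least 5.08-fold higher), PLAC8 (at least 5.29-fold), DAZAP2 (at least 4.3-fold), FCER1G, the Fc receptor gamma chain (at least 3.23-fold), and CYBA, a subunit of the NADPH oxidase (at least 3.13-fold), none of them detected in the efflux-low library. Among the highest in the efflux-low library were C1ORF110 (at least 69.0-fold), GSTTP2 (at least 87.3-fold), UGT2B7 (at least 62.1-fold), CYCSL1 (at least 98.8-fold) and MSX1, a homeobox gene (at least 56.5-fold), none detected in the efflux-high library. These bounds hold for quantile normalization alone, since the log2 difference of C1ORF110 went from -6.92 to -3.94, and that of MSX1 from -6.75 to -3.15, when arrays were centred on the median of all genes. In total, 4462 genes were 2-fold or more higher in the efflux-high library and 1458 lower, with a median of 1.47 over all 7452 genes, and with undetected genes held at the detection limit the balance turned to 428 higher and 1458 lower. The difference between the fractions had a Pearson correlation of 0.09 across genes with the sort drug difference (Spearman 0.08). The efflux-low library differed from mock-sorted treated cells in 6138 genes (1592 higher, 4546 lower) and from mock-sorted untreated cells in 6023 (1503 and 4520), which became 1592 and 418, and 1502 and 440, with undetected genes held at the detection limit.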

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

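The tests of explanations in this part were chosen after the result was seen. In the treated against untreated comparisons, 13 named genes were 2-fold or more higher in at least 1 comparison and 2-fold or more lower in another. The difference between the comparisons was not tested, since each has 1 library per arm. Of these, 5 were lower in the mock-sorted pair and higher at day 7, namely DDIT4 (-2.39 and 1.88), ALDOC (-1.89 and 1.71), PCK2 (-2.24 and 1.55), ASNS (-1.94 and 1.04) and ATF5 (-2.03 and 1.01). The following 6 metallothionein genes were lower in the mock-sorted pair and higher at day 17, while MT1F of the same family was higher in both (0.60 and 0.72): MT2A (-2.44 and 2.34), MT1H (-1.65 and 2.66), MT1G (-1.49 and 2.65), MT1A (-1.77 and 1.89), MT1X (-1.36 and 1.71) and MTE (-1.27 and 1.38), as was ENDOGL1, a mitochondrial exonuclease gene now called EXOG (-1.47 and 1.59, or at least 3.01-fold at day 17, since it was not detected at day 0). LGALS1 went the other way, at 1.84 in the mock-sorted pair and -1.14 at day 17.

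The endoplasmic reticulum and ATF4 stress-response list was lower in the mock-sorted treated library than in its untreated partner (median -0.31, percentile 0.2 of random lists), with 5 of 16 members lower and 1 higher (PPP1R15A, 1.68) by 2-fold or more. A general effect of 24 h vincristine would lower the list at day 1 of the bulk experiment too, but its median there was -0.02, at percentile 40.2. This answer depended on the scaling. Relative to all genes the day 1 median was -0.01, and -0.19 when arrays were centred on a median, where the sort pair had -0.31. A raised level in the mock-sorted untreated library would show against day 0, the other untreated library, and there the list had a median of 0.47, at percentile 99.9, with DDIT4 higher by 1.23. Both differences use the mock-sorted untreated library, so a chance high value there enters both. Under quantile normalization the pattern may rest on that library rather than on the drug. With centring, a general effect of the drug remains open. An effect of the drug that depends on the state of the culture was not tested.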

How the results depend on the processing

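The settings without the efflux-low library and with centring on genes detected in 8 libraries were chosen after the result was seen, and the others before. The drug fit pairs the treated with the untreated library of each experiment, and leaving out either pair of the drug fit leaves no degree of freedom for a test. All 5 drug calls kept their direction in each pair alone (CD14 3.26 and 2.19), which is no separate check, since they were called from these same pairs. The cause of the changes below was not tested. By construction, however, centring on a median moves all genes of a library together, and both centrings replace quantile normalization. Relative to quantile normalization, centring on the median of all genes shifted the all-gene median by -0.56 at day 1, 0.16 at day 2, -0.95 at day 7 and 0.33 at day 17, and centring on detected genes by 0.15 at day 1 and 0.18 at day 7. Answers to the comparisons stayed the same in 157 cases, moved in 77 and reversed in 5. Reversed here means a changed sign in a median or correlation whose 95% interval left out 0. That interval covers the spread over genes and not over libraries. By this definition, changes in the share of higher genes, given below, are not among the 5. Of the 5, 4 arose under the 2 centrings, which move all genes of a library together. Relative to all genes, the 118 genes kept their sign at day 7 (0.09 and 0.57 centred) and not at day 17 (0.07 and -0.05), and the 69 genes kept theirs at each day, while genes chosen anew after centring turned at day 1 (0.06). Of single named genes, 1216 values stayed the same, 101 moved, 17 were stronger, 20 weaker and 0 reversed. The 1216 include 11 values without the sort pair and 11 without the bulk pair, to which the same limit applies.

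The drug test, with 5 calls, gave 2 with an offset of 50, 9 in the authors' processed table, 12 for genes detected in every library, 8 without a detection filter, 2 without the efflux-low library (CCL2 and LGALS1), 75 with centring on the median of all genes (3 of the 5 kept), 125 with centring on detected genes, 0 without the experiment block, 1 without a trend and 3 with all 9 libraries in the fit. The 12 list calls became 0 with an estimated correlation, a form of the test that has 1 degree of freedom here and could hardly call any list. With centring on the median of all genes, 8 lists rose and 4 fell, against 9 and 3, and with centring on detected genes 7 rose and 5 fell. Of genes 2-fold or more different in both experiments, 22 became 11 without background correction, 8 with an offset of 50, 9 in the authors' table, 11 with detection in every library and 43 with centring on detected genes.

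The efflux fractions depended on the detection filter. Between efflux-high and efflux-low, 5920 genes became 595 for genes detected in both (29.6% higher in the efflux-high library, against 75.4%) and 9065 without a filter (51.6%). The efflux-low library against the mock-sorted treated library had 602 with detection in both (72.4% higher, against 25.9%), and against the untreated library 606 (70.1%, against 25%) and 9116 without a filter (48.3%). The efflux-high library against mock-sorted treated cells, at 661, had 412 without background correction, 387 with an offset of 50 and 355 in the authors' table. Against untreated cells, at 802, these were 500, 465 and 454.

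In the bulk series, 42, 107, 103 and 66 genes were 2-fold different at days 1, 2, 7 and 17. Without background correction these were 16, 51, 19 and 36, with an offset of 50 they were 15, 47, 17 and 33, and in the table of the authors they were 20, 62, 29 and 37. At 1.5-fold they were 375, 642, 677 and 643. Day 7 had 37 with detection in every library. Centring on the median of all genes gave 567 at day 1, 3244 at day 7 and 226 at day 17, and centring on detected genes 106 at day 1 and 401 at day 7. The share of higher genes, 73.8% at day 1, 41.7% at day 7 and 34.8% at day 17, was 1.8, 0.1 and 94.2% with the first centring, and 96.2 and 98.3% at days 1 and 7 with the second. At days 1 and 7 it was 86.7 and 88.2% with an offset of 50, 87.5 and 84.2% without background correction and 85.0 and 82.8% in the authors' table. With detection in every library it was 81.1% at day 7.

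For the genes higher in the mock-sorted pair, the medians of 0.43, 0.61, 0.08 and 0.09 became 0.01 at day 1, -0.39 at day 7 (reversed) and 0.27 at day 17 with centring on all genes, and 0.82, 0.83 at day 7 and -0.10 at day 17 (reversed) with centring on detected genes. At day 7 the median was 0.15 without background correction, 0.14 with an offset of 50 and 0.17 in the authors' table, which gave 0.18 at day 17. Genes selected at 1.5-fold gave 0.17 at day 1, 0.32 at day 2 and -0.03 at day 7 (reversed). For the genes lower in that pair, the medians of -0.08, -0.10, 0.42 and -0.04 became -0.57, 0.03, -0.27 (reversed) and 0.29 with centring on all genes, and 0.22 at day 1 (reversed) and 0.72 at day 7 with centring on detected genes. They were -0.18 at day 1 in the authors' table, and 0.23 at day 7 and -0.13 at day 17 with a 1.5-fold selection.

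The correlation with day 7, -0.14, was -0.16 without background correction, -0.17 with an offset of 50, -0.16 in the authors' table, -0.22 with detection in every library and 0.00 with either centring. The centrings differ from each other only by a constant per array, so their correlations are the same by construction and count as 1 result. A constant leaves a correlation across genes unchanged, so this change follows from leaving out quantile normalization. With day 1, 0.24 became 0.21 with either centring, with detection in every library and without a filter, and with day 2, 0.32 became 0.27 with detection in every library.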

Other observations

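The tests of explanations in this part were chosen after the result was seen, as were the metallothionein family and the comparison of the 2 untreated libraries. Metallothioneins, which bind zinc, copper and cadmium, lie at 16q13b. The median of 8 of these genes was -1.42 in the mock-sorted pair, where MT1F alone was higher (0.60), and 1.80 at day 17. At day 7 it was 0.99, and relative to all genes 1.00, or 0.78 when arrays were centred on a median. The mock-sorted untreated library had higher values than day 0, the other untreated library, for MT2A (2.66), MT1G (2.26), MT1H (2.12) and MT1A (1.87). It was also higher for DDIT4 (1.23), ASNS (1.25), PHGDH (0.78) and TRIB3 (0.57).

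Heat shock genes had medians of -0.54 at day 7 (percentile 0.0 of random lists) and 0.31 at day 17 (99.3). Ribosome biogenesis genes had medians of -0.20 at day 1 (0.0), -0.15 at day 7 (0.6) and 0.22 at day 17 (99.5). G1/S and replication genes had medians of -0.19 at day 1 (0.0) and 0.18 at day 17 (98.1). Oxidative phosphorylation genes had a median of 0.25 at day 17 (99.8). The size of these medians depended on the scaling. Relative to all genes, centring on a median changed oxidative phosphorylation at day 17 from 0.24 to 0.09. It changed ribosome biogenesis at day 7 from -0.14 to -0.41 and G1/S genes at day 1 from -0.18 to -0.37.

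For the 118 genes 2-fold or more higher in the sort pair, the median ratio of the day 1 to the sort difference was 0.26 (10th to 90th percentile -0.04 to 0.77), and 61 genes lay within 0.2 of it. The median ratio at day 2 was 0.40. These genes were chosen in the sort pair, so a ratio below 1 can follow from the choice alone. For the 31 genes 2-fold or more higher in the bulk pair, the median ratio of the sort to the day 1 difference was 1.04. A prediction that differences were compressed on the dim day 1 array had been met by these values and was then left out, after they were seen, to stay within 3 weighed patterns.

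The efflux-low library lay near background. Its median ribosomal protein gene stood 3.07 times above background and 0 of 44 reached the lowest of the other 8 libraries. A live cell state with low efflux and normal RNA content would have let them reach it if the array worked. The count uses the same signal by which this library stood out, so it is not a separate test and excludes nothing. Of the 1135 genes detected in the efflux-low library, 204 were detected in no other library, and its 100 brightest genes held 46.0% of the signal, against 18.0% in the mock-sorted treated library. Its mean raw intensity of 292.4 was like that of the brighter arrays, and F2R, among its brightest genes, read 66382 units against 11346 in the mock-sorted treated library. Little cellular RNA, which the value of 3.07 only restates, or a failed hybridization may account for this, and the 2 cannot be told apart.

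Of the genes detected in either comparison, 18 were 2-fold or more lower at both day 2 and day 17, among them ABCA1, LYZ, B2M, RPL14, RPL23 and CYP51A1. In 100 simulations of unchanged libraries that share day 0, 0.59 genes on average and at most 4 were lower in both. The spread per gene came from the drug fit, with its 1 residual degree of freedom, and the noise was normal. These simulations had on average 3.78 genes lower in a single comparison, against 54 measured at day 2 and 43 at day 17. Their spread may thus be too small, and they do not tell whether 18 is more than a shared day 0 library gives. For these 18 genes the mock-sorted untreated library was also lower than day 0 (median -1.08, 95% interval -1.25 to -0.48, 18 of 18 below 0), but the genes were chosen against the same day 0 library. A high level there would lower them at days 1 and 7 too, where the medians were -0.57 and -0.43 and LYZ stood at -0.04 and 0.94. A high level in that library and a lasting response to the drug, with a median of -0.18 (-0.53 to -0.05) in the sort pair, therefore cannot be told apart. Both intervals come from resampling genes with 1 library per arm and do not measure the spread between libraries. Dimmer arrays at days 2 and 17 would lower the raw 75th percentile, and the lower of their 2 ratios to day 0 was 0.93. That measure does not cover bright genes. Ribosomal protein genes had a median raw signal of 6085.8 at day 2 and 7259.7 at day 17, against 9092.9 at day 0. Dimmer arrays were therefore not excluded for bright genes.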
